A study of Canis lupus familiaris with 5 samples.

How the data were processed

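Nuclear RNA was measured by droplet single-nucleus RNA sequencing in cephalic vein of 2 dogs. Per the labels, a segment of undistended vein served as control (n = 2 libraries, dogs 1 and 2), a segment was taken after harvest with distension by injected saline, which together took approximately 30 minutes (n = 2, dogs 1 and 2), and a segment was taken 24 h after implantation as a carotid bypass graft (n = 1, dog 1). The authors deposited raw UMI counts per feature and barcode, made with Cell Ranger 7.0.0 per the file headers and the submitters' processing notes. The genome build is not given in the sources used here, so no coordinates are printed and no check on gene length or GC content was run. Gene names are those of the deposited feature tables. Of 35555 features, 33882 were found by name in a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, 17746 of the features carried a gene symbol rather than a locus name, and 524 shared a name with another feature. A group of 24 features that name no gene was left out of library sizes and tests; it held 7.70%, 11.5%, 5.22%, 5.42% and 0.588% of the UMIs in control dog 1, control dog 2, distended dog 1, distended dog 2 and grafted dog 1.

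Barcodes with at least 100 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept. The mitochondrial limit removed 0 nuclei, because the 13 mitochondrial protein genes held 0 counts in every library, so that this filter tested nothing. The gene limit removed 536 of 7391 barcodes and left 6855 nuclei. All kept nuclei were clustered together with scanpy 1.11.5, without batch integration: counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were chosen, and 20 principal components, 15 neighbours and a Leiden resolution of 0.8 gave 18 clusters. Clusters were named "-like" from 15 marker lists. A cluster stayed unnamed with under 3 detected markers or with a tie between lists. The same held where its 10 leading genes had no marker of its own list or more markers of another list. A marker counted as detected at 3 or more UMIs and a level at least 2 times that of the other clusters, limits set after the data had been seen. By these limits 5 clusters stayed unnamed, and their shares are given. Scrublet marked 42 nuclei (0.613%) as doublets. They were kept in the reported results and removed in an alternative. No correction was run for transcripts that come from outside a nucleus. Low levels of the markers of another class therefore cannot be assigned to the nuclei of a class.

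Nuclei are not replicates, so raw counts were summed per library over all nuclei (whole vein) and over the nuclei of each class, using libraries with at least 20 nuclei of the class. Sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test, two-sided), with all groups in the same fit and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. The lone grafted library was assumed to vary like the other libraries, whose spread supplied the error. In smooth muscle only the 2 controls supplied it. The test draws the spread of each gene towards that of all genes, more strongly in endothelial-like than in whole vein sums. For distended against control, SERPINE2 in whole vein (log2 fold change 3.98, SE 0.98) had an unadjusted edgeR p of 0.0026. MYO10 in endothelial-like sums (3.52, SE 0.87) had an unadjusted p of 5.3e-05 in the same test. Numbers of called genes are thus not on a like footing between whole vein and endothelial-like sums. Levels are given as TMM-normalised CPM. Folds against a group at 0 counts are lower limits computed from a floor of 3 counts over the group, and with 1 to 3 counts the ratio of pooled counts is given with its exact 95% counting interval. Fold limits and ratios were also computed without each library, at the same scaling; this was chosen after the data were seen, and no fold is given where 3 counts or fewer remain on both sides. Shares of nuclei over 0 carry exact Clopper-Pearson 95% intervals. For a share of 0 the limit given is instead that of 3 nuclei in the total, which is lower than the exact upper bound. Intervals and floors cover counting error only.

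The 18 gene lists, a list of ribosomal protein genes and the marker lists were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison that had at least 5 tested members. Every list call was repeated with an estimated correlation and with fry. Of the calls past the threshold with the preset, 0 held with an estimated correlation in any comparison and 0 with fry. With an estimated correlation, camera takes its p from the few residual degrees of freedom of the fit. Hardly any list could have passed there, so that setting neither backs nor counts against a preset call. Designs, lists, markers, filters and the rule for named genes were fixed before the data were examined. That rule took genes with a symbol, a consistent order of libraries between groups and the smallest adjusted p: up to 12 in each direction for whole vein, up to 6 for a class, and, by the smallest adjusted p alone without the order of libraries, up to 4 members of each list. Where fewer than 5 whole vein or class genes passed in a direction, the 5 with the smallest unadjusted p were taken as values only. Some genes that met these rules or are counted among the called genes are not reported here.

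Same-numbered libraries came from the same dog, per the labels, so the dog pairs the libraries. In a check of that pairing, the deviations of the dogs from the group means correlated across genes at -0.276 in whole vein, 0.00308 in endothelial-like and 0.0194 in fibroblast-like sums. The reported fit has no block, and the fit with the dog as a block is an alternative. Other alternatives were DESeq2 1.42.0, median-of-ratios scaling, no expression filter, each library left out, 200 genes per nucleus, doublets removed, ribosomal protein genes removed, thinned sums, thinned nuclei, and nuclei classed singly by marker UMIs. Chosen after the data were seen were the removal of 4 dominant features, the removal of either of 2 endothelial clusters, a crossed block, shares without each library, lists tested within classes, and the test of graft effects between classes.

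The tests were tried on simulated counts with the means and sizes of the real libraries and 200 changed genes. At a fold of 16, 46.3% of changed genes were recovered for whole vein distended against control and 16.4% for grafted against control, 55.2% for each of the endothelial comparisons, 16.4% and 13.4% for the fibroblast comparisons, and 83.6% for smooth muscle grafted against control. At a fold of 4 the recovered share lay between 0% (fibroblast, grafted) and 19.4% (smooth muscle, grafted). Smooth muscle distended against control and both macrophage comparisons had too few nuclei for a test. Spatial samples of the study and other dogs were not analysed here.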

Results

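Vein used as a bypass graft is distended during harvest and is then exposed to arterial flow, and the series compared nuclei of canine cephalic vein before and after these steps. Undistended control vein came from dogs 1 and 2, distended vein from the same dogs, and a vein graft taken 24 h after bypass from dog 1. The deposited libraries held 2337436 UMIs in 1048 barcodes for control dog 1, 1305862 in 1234 for control dog 2. They held 2667701 in 2162 for distended dog 1, 410604 in 242 for distended dog 2, and 11302558 in 2705 for grafted dog 1. After filtering, 765, 1036, 2108, 241 and 2705 nuclei remained in that order, with a median of 359, 241, 444, 433 and 1562 detected genes. The 4 features LOC119877772, LOC119877773, LOC119877774 and LOC119877775 took 70.4% and 61.4% of all UMIs in the control libraries, 38.5% and 26.5% in the distended libraries, and 2.98% in the graft. Ribosomal protein transcripts took 2.70%, 0.556%, 0.544%, 9.29% and 6.09% of the UMIs left without those features.

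Endothelial-like nuclei were the largest class in both control libraries, at 81.2% (95% exact interval 78.2 to 83.9) in dog 1 and 49.1% (46.0 to 52.2) in dog 2. Their share was 27.4% (25.5 to 29.3) and 21.2% (16.2 to 26.9) in the distended veins of dogs 1 and 2, and 38.0% (36.1 to 39.8) in the graft. In control dog 2, 413 endothelial-like nuclei lay in cluster 0, whose leading genes included the globin HBM. Clustered without the 4 dominant features, a cluster also led by HBM among others (419 control dog 2 nuclei) stayed unnamed. So did a cluster that held 967 grafted nuclei, so these endothelial shares depend on the clustering. Fibroblast-like nuclei held 5.88% and 36.6% of control, 57.1% and 20.7% of distended and 29.2% of grafted nuclei. Smooth muscle-like nuclei held 5.49% and 1.93% of control, 2.23% and 0.415% of distended and 1.37% of grafted nuclei. Macrophage/monocyte-like nuclei, led by F13A1, TIMD4, MRC1 and CD163, held 1.18% and 2.51% of control, 4.27% and 1.66% of distended and 0.0739% of grafted nuclei, the last being 2 of 2705. An unnamed cluster with 8 macrophage and 8 neutrophil markers held 447 further grafted nuclei.

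The endothelial share was lower by -40.9 percentage points in distended and by -27.2 in grafted than in control vein, against an SD of 22.7 between the controls. For fibroblast-like nuclei the differences were 17.7 and 8.01 points (control SD 21.7), for smooth muscle-like nuclei -2.39 and -2.34 (SD 2.52), and for macrophage/monocyte-like nuclei 1.12 and -1.77 (SD 0.943). These are values only, without a test. Without control dog 1 the endothelial differences were -24.9 and -11.2, those of fibroblasts 2.32 and -7.34 and those of smooth muscle -0.608 and -0.563. Without control dog 2 the same differences were -56.9 and -43.2, 33.0 and 23.4, and -4.17 and -4.12. The fibroblast difference of distended vein was -0.486 without distended dog 1 and 35.8 without distended dog 2, where that of smooth muscle was -1.48. The macrophage/monocyte difference of distended vein was 0.455 without control dog 1, 1.79 without control dog 2, -0.183 without distended dog 1 and 2.43 without distended dog 2, and that of the graft was -1.10 without control dog 2. The endothelial difference of distended vein was -18.3 at resolution 0.4, where distended dog 2 stood at 72.6%, and with nuclei thinned to 200 UMIs and classed singly the endothelial differences were 1.24 and 4.21. The macrophage/monocyte difference of the graft turned to 7.77 at resolution 1.5, to 5.999 with nuclei classed singly by markers and to 2.10 with thinned nuclei. Thinned nuclei kept the 4 dominant features among their 200 UMIs. Those features took 70.4% and 61.4% of control, 38.5% and 26.5% of distended and 2.98% of grafted UMIs. Thinning thus did not even out the UMIs of other genes, and whether the changes of sign come from that was not tested.

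Unnamed clusters held 5.49%, 6.85%, 3.46%, 56.0% and 31.3% of nuclei in control dogs 1 and 2, distended dogs 1 and 2 and the graft.

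**Figure D1:**
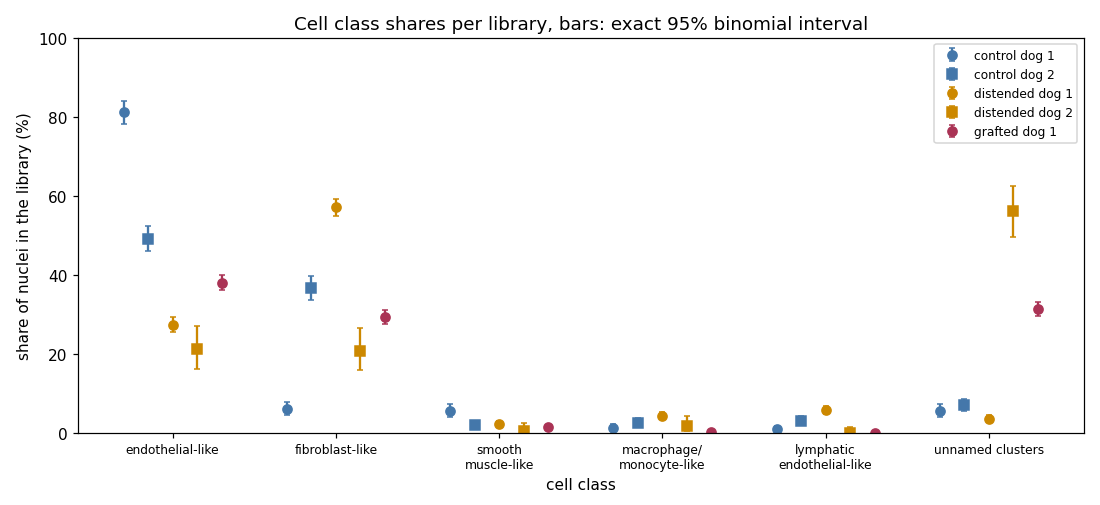
Share of nuclei (percent, vertical axis) in each cell class for the 5 libraries, coloured by group with a symbol per dog; bars are exact 95% binomial intervals. The endothelial-like points of the controls, 81.2% and 49.1%, lie above those of the other libraries, and unnamed clusters reach 56.0% in distended dog 2.

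In whole vein sums, distended vein held higher levels of SERPINE2, an inhibitor of serine proteases, at 56.2 ± 45.2 CPM (SD, n = 2) against 3.61 ± 2.01 in control. NTN4, a netrin of the basement membrane, stood at 119 ± 9.37 against 23.0 ± 7.77 CPM, FKBP10, a collagen chaperone, at 36.3 ± 25.0 against 2.77 ± 0.823, and C17H1orf54 at 30.9 ± 2.05 against 3.32 ± 0.0478. BCAT1, a branched-chain aminotransferase, had 78 counts against 2 (ratio 18.2, interval 4.86 to 153). On the lower side, the transcription factor SOX6 stood at 2.20 ± 0.574 against 61.9 ± 59.6 CPM and ITIH4 at 26.4 ± 14.4 against 136 ± 45.8. C3H4orf19 stood at 6.39 ± 1.13 against 36.5 ± 4.17, INHBA, a subunit of activin, at 42.2 ± 11.4 against 183 ± 109, and the neuronal nitric oxide synthase NOS1 at 1.12 ± 1.58 against 17.7 ± 1.31. These are values, not calls: edgeR called 0 of 13170 genes, with 186 at an unadjusted p under 0.05, and DESeq2 called 1. Without distended dog 1 the count was 219. The ratio of BCAT1 came to 0.395 of its size without control dog 1, to 0.403 without control dog 2 (a limit, with 0 counts left) and to 1.79 times its size without distended dog 1.

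Among lists tested in distended against control whole vein, 7 were called higher and 5 lower with the preset correlation. Of these 0 held with an estimated correlation (lowest adjusted p = 0.809 with an estimated correlation), a setting that hardly any list could pass. Cell cycle genes had a median log2 fold change of 1.64 over 33 members (adjusted p 1.91e-05), matrix proteases and their inhibitors of 0.90 over 15 (0.00179), and extracellular matrix genes of 0.54 over 38 (0.0165; 0.0779 with the dog as a block). Ribosomal protein genes had a mean of 1.52 over 79 members (3.43e-05). Their share of UMIs without the dominant features was 2.70% and 0.556% in control, and 0.544% and 9.29% in distended dogs 1 and 2. Only distended dog 2 thus lay above the controls, and distended dog 1 lay below both. Smooth muscle contractile genes had a median of -0.71 over 26 members (6.04e-06, but 0.584 without distended dog 2) and leukocyte adhesion genes -1.74 over 23 (0.0138). Heat shock genes, at 0.91 over 26, were called with the block (0.0120) and not without it (0.139). Marker lists moved in the same libraries: fibroblast markers 1.29 (0.000145), lymphatic endothelial 1.53 (0.000145), macrophage 1.32 (0.0175), endothelial -0.48 (0.00179), smooth muscle -0.73 (0.000145, but 0.782 without distended dog 2) and neutrophil -2.78 (0.0249). By shares of nuclei, only distended dog 1 lay above both controls for fibroblast-like (57.1%), lymphatic endothelial-like (5.60%) and macrophage/monocyte-like nuclei (4.27%). Distended dog 2 stood at 20.7%, 0 of 241 nuclei and 1.66%. An unnamed cluster with 8 neutrophil markers held 24 nuclei in control dog 2 and 0 in control dog 1. With thinned sums the adjusted p was 0.133 for matrix proteases, 0.764 for extracellular matrix and 0.143 for leukocyte adhesion genes. It was 0.278, 0.967 and 0.143 for fibroblast, macrophage and neutrophil markers. Without the dominant features it was 0.185 for leukocyte adhesion genes and 0.0696 for neutrophil markers. In each of these lists 0 members were called over all genes and 0 when adjusted over the list alone.

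In grafted against control whole vein, RGS4, a regulator of G protein signalling, had 1708 counts in the graft and 0 in the controls (at least 39.6-fold higher). GAP43, a growth cone protein, had 1205 and 0 (at least 27.9-fold higher). PHLDA1 stood at 270.4 CPM against 7.52 ± 5.98 (SD, n = 2). BCAT1 had 3121 counts against 2 (ratio 108, interval 30.0 to 896) and the potassium channel KCNH1 2476 against 3 (ratio 57.3, interval 19.6 to 278). Lower in the graft were ITIH4 at 3.78 CPM against 136 ± 45.8, ATP2A3, a calcium pump of the endoplasmic reticulum, at 0.875 against 108 ± 28.2. The transcription factor FOXC1 stood at 12.9 against 671 ± 40.1, the sodium channel SCN1A at 0.276 against 38.3 ± 32.7, and GAS2L2 at 0.691 against 38.8 ± 2.12. edgeR called 0 of 13170 genes, with 1162 at an unadjusted p under 0.05, and DESeq2 called 26 higher and 90 lower. The limits of RGS4 and GAP43 came to 0.395 of their size without control dog 1 and 0.605 without control dog 2, and the ratio of BCAT1 to 0.395 and 0.403. Without distended dog 1 the edgeR count was 646 and without distended dog 2 it was 419.

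Of the lists in that comparison 5 were called higher and 6 lower, and 0 held with an estimated correlation (lowest adjusted p = 0.785 with an estimated correlation). Higher were cell cycle (median log2 fold change 2.21, adjusted p 4.92e-05), ribosomal protein (1.71, 4.92e-05), unfolded protein response (1.20, 0.0116), NF-kB inflammatory response (0.71, 0.0193) and leukocyte adhesion genes (0.33, 0.0425, but 0.113 without distended dog 2). Lower were smooth muscle contractile (-1.57, 4.92e-05), interferon response (-1.39, 0.000485), flow-responsive endothelial (-1.08, 0.0141) and immediate early genes (-1.57, 0.0338; 0.137 with the dog as a block), with smooth muscle markers (-1.76, 0.000681) and endothelial markers (-0.64, 0.0219). The block also brought in oxidative stress and metal response genes (0.0142; 0.0923 without it), heat shock genes (0.0414; 0.303) and neutrophil markers (0.000838; 0.387), whose median was -0.84 although the test pointed up. Immediate early genes had an adjusted p of 0.0654 without the dominant features, and leukocyte adhesion genes of 0.116 with thinned sums. All of these lists had 0 members called over all genes and 0 adjusted over the list alone.

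Set against distended vein, the graft held more RGS4, with 1708 counts against 1 (ratio 255, interval 45.7 to 10072), and more of the metallothionein MT1E, with 803 counts against 0 (at least 39.9-fold higher). ITGA8, an integrin subunit, stood at 81.0 CPM against 3.85 ± 0.358 (SD, n = 2), PHLDA1 at 270.4 against 13.8 ± 5.86, and TFPI2, a Kunitz-type protease inhibitor, at 119 against 2.88 ± 3.55. Lower were TMSB4X, an actin-sequestering peptide, at 9.40 CPM against 136 ± 21.4, IGFBP5 at 1.34 against 71.7 ± 70.9, and TCIM at 0.783 against 34.1 ± 30.4. KRT7 had 0 counts against 81 (at least 181-fold lower), and MARCHF4 2 counts against 35 (ratio 117, interval 30.1 to 1007). Distended dog 1 held 80 of the 81 KRT7 counts, and without it the 1 count left gives no fold. Without that library RGS4 was at least 14.6-fold and MT1E at least 6.86-fold higher. edgeR called 0 of 13170 genes, with 725 at an unadjusted p under 0.05, and DESeq2 called 9 higher and 23 lower. The edgeR count was 6 without distended dog 1 and 432 without distended dog 2. With the preset correlation 7 lists were called higher and 9 lower, led by interferon response genes (median log2 fold change -1.65, adjusted p 5.39e-05) and leukocyte adhesion genes (2.27, 0.000182), and 0 held (lowest adjusted p = 0.774 with an estimated correlation). Among marker lists, neutrophil markers were higher (2.14 over 8 members, 0.0218), and fibroblast (-2.61, 0.00784), lymphatic endothelial (-1.96, 0.0267) and smooth muscle markers (-1.36, 0.0409) lower, each at 0.774 with an estimated correlation. Pericyte markers, at -1.43 (0.0409), had an adjusted p of 0.194 with the dog as a block and of 0.0912 without distended dog 2. With thinned sums lymphatic endothelial markers stood at 0.131 and smooth muscle markers at 0.522. In these lists 0 members were called over all genes, and adjusted over the list alone 1 smooth muscle marker rose.

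In endothelial-like nuclei, distension went with higher levels of a small set of genes. HMGA2, a chromatin protein of embryonic and proliferating cells, had 32 counts in distended and 0 in control vein (at least 9.18-fold higher, adjusted p 1.91e-06), 30 of them in dog 2. KDR, a VEGF receptor, had 23 counts against 0 (at least 6.60-fold higher, adjusted p 0.0119). The limits of HMGA2 and KDR came to 0.350 of their size without control dog 1 and 0.650 without control dog 2. Without distended dog 1 they were at least 58.2-fold and 17.5-fold, and without distended dog 2 the 2 counts of HMGA2 give no fold. COL15A1, a collagen of the basement membrane zone, rose by a log2 fold change of 4.21 (SE 0.84, adjusted p 0.000624), from 6.96 ± 2.94 to 119 ± 47.0 CPM (SD, n = 2). The unconventional myosin MYO10 (log2 fold change 3.52, SE 0.87) also rose. The phospholipase PLCB1 was called higher (2.99, SE 0.74), with 351 of its 361 distended counts in dog 1. It was 1.11 without distended dog 1 and turned to -0.65 without the cluster led by DACH1. The 6 genes picked by the rule as higher, these 5 among them, lost their calls without control dog 1 and without control dog 2. Their direction stayed the same in both fits. With the dog as a block 2 of the 6 kept their call.

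With little weight on a gene's own spread between libraries, the test called 15 genes higher and 9 lower of 10388. Among the lower ones was a red cell transcript, the globin HBM, with 139 counts in control dog 2 and 0 in the other libraries. HBM, LOC480784 and SOX6 were no longer tested without the cluster whose leading genes included HBM. Among the members of the lists, VCAM1, a leukocyte adhesion receptor, fell by 4.90 on the log2 scale (adjusted p 6.14e-05), with 104 of its 109 control counts in dog 2, and the interferon-induced factor IRF1 fell by 3.75 (adjusted p 0.00370), with 73 of 75 in dog 2. Control dog 1, at 8.13 and 3.25 CPM, lay below distended dog 2 for VCAM1 (12.3) and below distended dog 1 for IRF1 (10.7). No symbol-bearing gene passed the library order for a lower call, and the values nearest to it were CGNL1, a junction protein, at 15.2 ± 4.13 CPM against 115 ± 0.633, and LTBP2 at 4.67 ± 2.08 against 41.9 ± 46.5. SCN1A stood at 9.75 ± 12.3 against 51.1 ± 38.1, IQCN had 1 count against 25 (ratio 29.0, interval 4.75 to 1193) and SLC22A23 0 against 20 (at least 7.75-fold lower). Control dog 2 held 24 of the 25 and 18 of the 20 counts, and without it the 1 and 2 counts left give no fold. Without control dog 1 the values were 2.74 and 2.57 times their size, and without distended dog 1 limits of 1.43 and 1.15. The lists of angiogenic and activated endothelial genes (1 of 24 members called, KDR, and 3 higher adjusted over the list alone), matrix proteases (0 of 13, and 3 adjusted over the list alone) and cell cycle genes (0 of 24, and 2 adjusted over the list alone) were higher, with adjusted p of 9.33e-05, 9.33e-05 and 0.00248. Their adjusted p was 0.792, 0.792 and 0.876 with an estimated correlation. The first was at 0.630 with thinned sums and the last at 0.0892 without the dominant features. ANGPT2, a ligand of the TIE2 receptor, had 40 counts against 2 (ratio 17.2, interval 4.46 to 147), and ADAM12 stood at a log2 fold change of 3.27 (SE 0.90), neither of them called. The ratio of ANGPT2 came to 0.350 of its size without control dog 1 and 0.433 without control dog 2, and without distended dog 1 the counts, 3 against 2, give no fold.

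The clusters behind these sums differed. Control endothelial-like nuclei lay in clusters 0 and 1 (336 and 279 nuclei in dog 1, 413 and 94 in dog 2). Those of distended dog 1 lay mostly in cluster 1 (403 of 577), and those of distended dog 2 in cluster 5, which DACH1 led (26 of 51), and cluster 14 (17). The 4 dominant features took 75.9% and 66.2% of endothelial UMIs in the controls, 44.8% and 34.7% in the distended libraries. The count of 24 became 7 with the dog as a block, 3 in DESeq2, 13 without the expression filter, 0 with the dominant features removed, 0 with nuclei classed singly by markers and 4 with thinned sums. It was 12 without control dog 1, 0 without control dog 2, 151 without distended dog 1 and 0 without the graft.

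Endothelial-like nuclei of the graft differed from control in 351 genes that rose and 352 that fell of 10388. FSIP1 had 6333 counts in the graft and 0 in the controls (at least 204-fold higher, adjusted p 2.98e-12). PHLDA1 had 2283 and 0 (at least 73.6-fold), BCAT1 1553 and 0 (at least 50.1-fold), HMGA2 1269 and 0 (at least 40.9-fold) and RGS4 1011 and 0 (at least 32.6-fold). SLC39A14, a zinc and manganese transporter, had 2629 counts against 3 (ratio 84.8, interval 29.0 to 412). Falling genes were led by the calcium pump ATP2A3 (log2 fold change -7.59, SE 1.17, adjusted p 7.40e-08), the scaffold protein AHNAK2 (-7.13, SE 1.17), the deubiquitinase USP2 (-6.99, SE 1.19), ANKRD55 (-6.70, SE 1.13) and CLEC3B, the plasminogen-binding tetranectin (-6.44, SE 1.10). SCN1A had 1 count against 56 (ratio 579, interval 99.7 to 23259), 0.408 of that size without control dog 1. For FSIP1, PHLDA1, BCAT1, HMGA2, RGS4 and SLC39A14 the values came to 0.350 of their size without control dog 1 and 0.650 without control dog 2.

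Of 33 immediate early genes, which are induced within minutes of a stimulus, 13 fell and 1 rose, and 19 were not called. Adjusted over the list alone 20 fell and 2 rose. The log2 fold change was -6.55 for JUN (SE 1.37), -5.37 for EGR1 (SE 1.13) and -5.11 for ATF3 (SE 1.01). FOSB had 2 counts against 192 (ratio 992, interval 271 to 8250.0). The graft thus lay below control dog 2 and not below control dog 1 for FOSB. Control dog 2 held 192 of the 192 control counts of FOSB, so that its ratio is 2.85 times its size without control dog 1 and none is left without control dog 2. It also held 222 of 237 counts of EGR1, 79 of 82 of ATF3 and 550 of 685 of JUN. The list had an adjusted p of 0.00203, 0.0896 with the dog as a block, and an adjusted p of 0.729 with an estimated correlation. Of 24 cell cycle genes 7 rose and 0 fell (11 and 1 adjusted over the list alone). The helicase BRIP1 stood at 550 counts against 1 (ratio 53.2, interval 9.51 to 2106), the replication factor MCM3 at 407 against 1 (ratio 39.4, interval 7.03 to 1559). HELLS stood at 539 against 3 (ratio 17.4, interval 5.92 to 84.6) and ATAD2 at a log2 fold change of 2.84 (SE 0.80). Without control dog 1 the ratios of BRIP1, MCM3 and HELLS came to 0.350, 0.117 and 0.526 of their size, and without control dog 2 to 0.217, 0.650 and 1.95. The cell cycle list had an adjusted p of 2.24e-05, and of 0.729 with an estimated correlation.

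Genes of the NF-kB response had 2 members that rose and 1 that fell of 26 (2 and 1 adjusted over the list alone; adjusted p 0.0241, adjusted p = 0.729 with an estimated correlation). CSF3, the granulocyte colony-stimulating factor, rose by a log2 fold change of 5.65 (SE 0.92), the neutrophil chemoattractant CXCL8 had 725 counts against 3 (ratio 23.4, interval 7.97 to 114), and VCAM1 was called lower (-2.74, SE 0.87). That call rests on control dog 2, with 104 of the 109 control counts, since the graft stood at 23.5 CPM and control dog 1 at 8.13. The ratio of CXCL8 came to 0.350 of its size without control dog 1 and 0.650 without control dog 2. With thinned sums the list was at 0.194. Interferon response genes were lower (adjusted p 0.00203, adjusted p = 0.729 with an estimated correlation), with IRF1 (-3.65) and MX1 (-3.97) as the 2 called lower of 20 (3 adjusted over the list alone). For IRF1 the call rests on control dog 2, with 73 of the 75 control counts, since the graft stood at 8.58 CPM and control dog 1 at 3.25. Leukocyte adhesion genes were higher (0.0241, adjusted p = 0.729 with an estimated correlation) with LYN, a Src family kinase, the 1 that rose of 11 (3 adjusted over the list alone). Matrix proteases and inhibitors were higher (0.0366, adjusted p = 0.729 with an estimated correlation): ADAMTS9 (4.48, SE 0.89), TIMP1 (3.89, SE 0.88) and ADAM12 (3.02, SE 0.93) rose and TIMP3 fell by 4.26 (SE 1.06). The counts were 3 and 1 adjusted over the list alone. Without the dominant features leukocyte adhesion genes and matrix proteases were both at 0.0753. Neutrophil markers, with 0 of 5 called over all genes and 0 adjusted over the list alone, had an adjusted p of 0.0951, and 0.00651 with the dog as a block. No list of this comparison lay under 0.729 with an estimated correlation and no block.

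Other lists had called members without a call of the list. Of 22 flow-responsive endothelial genes KDR rose (245 counts against 0, at least 7.90-fold) and 4 fell, among them the shear-induced factor KLF4 (-4.81, SE 1.15), the tight junction gene CLDN5 (-4.14, SE 1.19) and the venous identity factor NR2F2 (-3.24, SE 1.00). Adjusted over the list alone the counts were 2 and 5. Of 31 extracellular matrix genes 5 rose and 4 fell (6 and 5 adjusted over the list alone), with COL15A1 (4.49, SE 0.89) and VCAN (3.95, SE 0.86) higher and COL14A1 (-4.51, SE 1.11) and COL3A1 (-3.52, SE 0.92) lower. Of 24 angiogenic genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), ANGPT2 with 798 counts against 2 (ratio 38.6, interval 10.7 to 319) and STC1 falling by 3.62 (SE 0.93). Of 27 TGF-beta response genes 4 rose and 2 fell (10 and 3 adjusted over the list alone), RUNX1 by 4.20 (SE 0.97) and ID1 by 2.91 (SE 0.79). Of 13 coagulation genes THBS1 (3.09, SE 0.89), F2R (2.64, SE 0.86) and SERPINE2 (161 counts against 0, at least 5.19-fold) rose and F8 fell by 3.88 (SE 0.99), against 6 and 2 adjusted over the list alone. Among 18 oxidative stress and metal response genes MT2A (4.13, SE 0.93), SLC39A14 and SLC7A11 (240 counts against 0, at least 7.74-fold) rose and GPX1 fell by 3.02 (SE 0.96), 3 and 1 also adjusted over the list alone. Without control dog 1 the limits of KDR, SERPINE2 and SLC7A11 were 2.77, 1.82 and 2.71, and without control dog 2 they were 5.13, 3.37 and 5.03. The ratio of ANGPT2 came to 0.350 and 0.433 of its size.

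The grafted endothelial-like nuclei lay in cluster 14 (962 of 1027), which counts RGS4 and ITGA8 among its leading genes, and the control nuclei in clusters 0 and 1. Median UMIs were 3908 in the graft against 1403 and 770.0 in control dogs 1 and 2. Without the dominant features the medians were 3828 against 425 and 310. Those features took 1.96% of endothelial UMIs in the graft. Clustered without these features, the cluster with RGS4 and ITGA8 among its leading genes (967 grafted nuclei) stayed unnamed. The class of these nuclei thus depends on the clustering, and no gene test was run with that clustering. DESeq2 gave no adjusted p for 4028 of the 10388 genes. The count of 703 was 489 with the dog as a block, 175 in DESeq2, 313 with the dominant features removed and 68 with thinned sums. It was 0 with nuclei classed singly by markers, where 1187 genes had an unadjusted p under 0.05. It was 224 without control dog 1, 192 without control dog 2, 1073 without distended dog 1, 1105 without distended dog 2 and 370 without cluster 0.

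**Figure D2:**
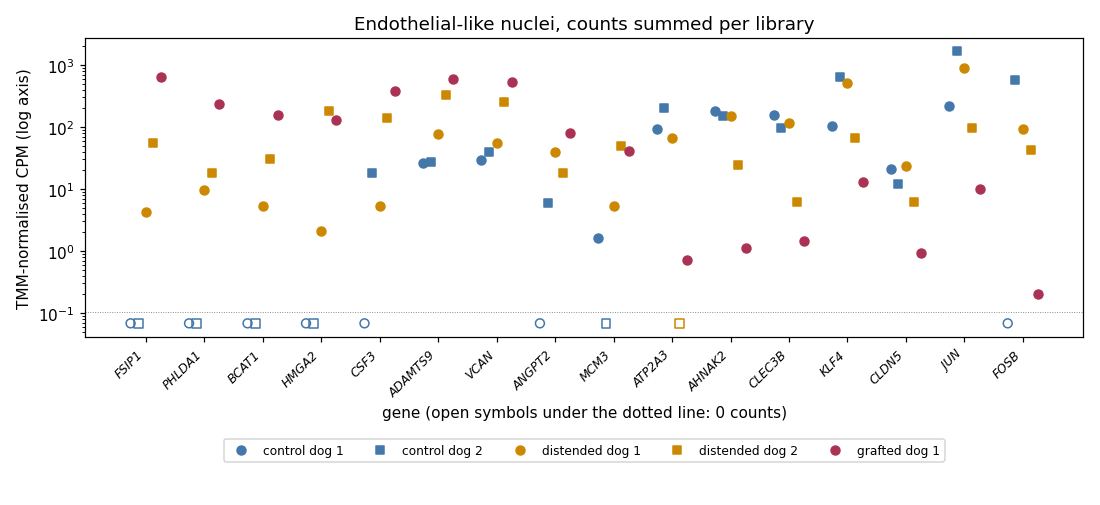
TMM-normalised CPM (log axis) of 16 genes in endothelial-like sums, with a point per library coloured by group and shaped by dog, and open symbols under the dotted line for 0 counts. The graft lies above both controls for the genes from FSIP1 to MCM3 and below both for ATP2A3 to JUN; FOSB had 0 counts in control dog 1 and 579 CPM in control dog 2.

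In fibroblast-like nuclei, the distended libraries held KCNH1 at 31 counts against 0 in control (at least 1.54-fold higher) and C17H1orf54 at 60 against 0 (at least 2.98-fold). The transcription factor SOX4 stood at 33 against 1 (ratio 4.92, interval 0.823 to 199.96) and LTBP1, which binds latent TGF-beta, at 116 against 2 (ratio 8.64, interval 2.34 to 72.2). Without control dog 2 these values were lower limits of 0.185, 0.358, 0.197 and 0.692 in that order, which neither show nor exclude a rise. Without distended dog 1 they came to 10.2, 2.30, 13.7 and 3.39 times their size, and without distended dog 2 those of KCNH1 and SOX4 to 0.510 and 0.319. HSP70 stood at 335 ± 385 CPM (SD, n = 2) against 17.2 ± 24.4. SHISA3 stood at 13.1 ± 18.5 against 122 ± 54.2 CPM and VWF, an endothelial glycoprotein, at 14.3 ± 20.2 against 111 ± 37.9. The DNA repair factor XPC stood at 9.91 ± 14.0 against 61.2 ± 27.1 and NOM1 at 49.4 ± 49.0 against 245 ± 70.3. None of these was called: edgeR called 0 of 7222 genes, with 84 at an unadjusted p under 0.05, and DESeq2 called 0. Without distended dog 2 the edgeR count was 2.

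Fibroblast-like lists called lower in distended vein were NF-kB response genes (median log2 fold change -0.51, adjusted p 1.90e-06, 0.675 with the dog as a block), leukocyte adhesion genes (-0.15 with a mean of 0.53, 0.00993, block 0.784) and endothelial markers (-1.72, 0.00123, block 0.0210). Interferon response genes were higher (1.16, 0.0386, block 0.730). The interferon list was at 0.954 without the dominant features and the NF-kB list at 0.868 with thinned sums. All 4 had an adjusted p of 0.834 with an estimated correlation, and 0 members called over all genes or adjusted over the list alone. With the block, ribosomal protein genes (0.000163; 0.972 without it), immediate early genes (0.0118; 0.0620), contractile genes (0.0167; 0.0620) and smooth muscle markers (0.0210; 0.356) were also called. With an estimated correlation and no block, the lowest adjusted p of any list in this comparison was 0.834. Fibroblast-like nuclei of the controls and of distended dog 1 lay in clusters 3, 4 and 10, and those of distended dog 2 in cluster 16 (45 of 50). The dominant features took 87.2% and 66.6% of fibroblast UMIs in the controls, 35.6% and 27.8% in the distended libraries and 4.85% in the graft.

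Grafted fibroblast-like nuclei had 25 genes that rose and 104 that fell of 7222 against control. TFPI2 had 1857 counts in the graft and 0 in the controls (at least 33.6-fold higher, adjusted p 0.00518). KCNH1 had 2020 and 0 (at least 36.6-fold), HMGA2 1092 and 0 (at least 19.8-fold) and GAP43 1020 and 0 (at least 18.5-fold). MYO10 had 2963 against 1 (ratio 161, interval 28.9 to 6358), and the transcription factor RUNX1 rose by a log2 fold change of 5.77 (SE 1.47, adjusted p 0.0157). LIMS2, a focal adhesion adaptor, had 0 counts against 30 (at least 184-fold lower), the complement gene C7 0 against 25 (at least 153-fold) and CCDC85A 0 against 12 (at least 73.7-fold). TIMP2_7 had 1 count against 49 (ratio 902, interval 155 to 36354), the semaphorin SEMA3B 1 against 70 (ratio 1289, interval 224 to 51626) and SHISA3 1 against 30 (ratio 552, interval 91.8 to 22536). Control dog 2 held 29 of the 30 counts of LIMS2, 47 of 49 of TIMP2_7, 68 of 70 of SEMA3B, 28 of 30 of SHISA3 and 9 of 12 of CCDC85A. Without it these genes have 3 counts or fewer and give no fold. Without that library TFPI2, KCNH1, HMGA2, GAP43 and MYO10 were higher by at least 4.04, 4.39, 2.37, 2.22 and 6.44-fold.

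Members of the immediate early list fell in these nuclei, FOSB at a log2 fold change of -6.23 (SE 1.70), EGR1 at -6.15 (SE 1.83) and BTG2 at -4.58 (SE 1.38). These were 3 of 30 over all genes, against 13 adjusted over the list alone, and control dog 2 held 65 of 66, 176 of 184 and 22 of 22 of their control counts. For BTG2 the graft, at 3.57 CPM, did not lie below control dog 1, which had 0 counts. The list had an adjusted p of 1.29e-07, and an adjusted p of 0.609 with an estimated correlation. The other 8 list calls had an adjusted p between 0.609 and 0.681 with an estimated correlation. Ribosomal protein genes were higher (median log2 fold change 1.70, adjusted p 6.64e-11, 0 of 76 members called), as were oxidative stress and metal response genes (1.76, 0.0421, 0 of 11 called and 1 adjusted over the list alone). Lower were contractile genes (-2.10, 0.000190, with the kinase MYLK the 1 of 16 that fell and 5 adjusted over the list alone) and flow-responsive genes (-2.09, 0.00843, 0 of 11 and 3 adjusted over the list alone). So were interferon response genes (-0.83, 0.0194, 0 of 11 and 0 adjusted over the list alone) and extracellular matrix genes (-0.74, 0.0471, 1 of 35 higher, and 2 higher and 6 lower adjusted over the list alone). Fibroblast markers (-2.79, 0.00526) were lower in the same nuclei, where 4 of 17 fell over all genes, and 1 rose and 5 fell adjusted over the list alone. Smooth muscle markers were lower too (-2.76, 0.000190), with 1 of 9 falling and 4 adjusted over the list alone. With thinned sums ribosomal protein and contractile genes were both at 0.105, extracellular matrix genes at 0.0516 and fibroblast markers at 0.141. Without the dominant features extracellular matrix genes were at 0.179 and interferon response genes at 0.103.

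Of 24 TGF-beta response genes RUNX1, TNC (602 counts against 0, at least 10.9-fold) and LTBP1 (1696 against 2, ratio 46.1, interval 12.7 to 381) rose, 3 also adjusted over the list alone. Of 13 matrix protease and inhibitor genes TIMP1 (503 against 0, at least 9.11-fold) and the aggrecanase ADAMTS4 (472 against 0, at least 8.54-fold) rose and TIMP3 fell by 6.35 (SE 1.69), against 3 and 1 adjusted over the list alone. Without control dog 2 the limits were 1.31 for TNC, 3.69 for LTBP1, 1.09 for TIMP1 and 1.03 for ADAMTS4. With the dog as a block, angiogenic (0.0208; 0.0543 without it), hypoxia (0.0382; 0.173), leukocyte adhesion (0.0243; 0.243) and NF-kB response lists (0.0413; 0.621) were called. No list of this comparison lay under 0.609 with an estimated correlation and no block.

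All but 1 of the 791 grafted fibroblast-like nuclei lay in cluster 15, led by GAP43, TFPI2 and KCNH1 among others, and 0 in the clusters of the control nuclei. The count of 129 was 0 with the dog as a block, 51 in DESeq2, 22 without the expression filter, 41 at 200 genes per nucleus, 82 with nuclei classed singly, 38 with the dominant features removed and 0 with thinned sums. It was 70 without control dog 1, which held 45 such nuclei, 3 without control dog 2, and 245 without distended dog 2. With median-of-ratios scaling 31.5% of the called genes were higher, against 19.4%, and the median of all genes moved by 0.37 on the log2 scale. DESeq2 gave no adjusted p for 4340 of the 7222 genes. The fit at 200 genes per nucleus lacked control dog 1, which kept 7 such nuclei.

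**Figure D3:**
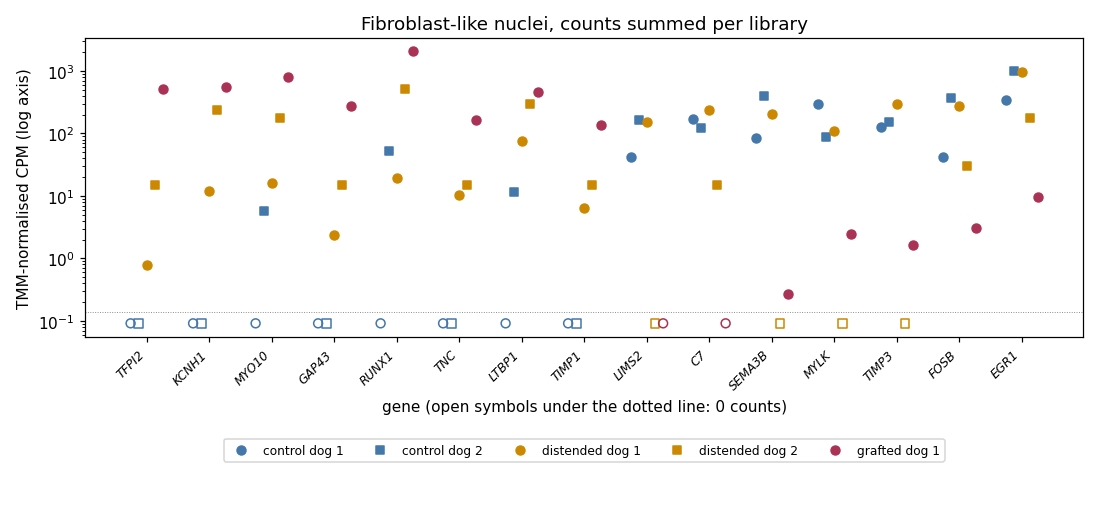
TMM-normalised CPM (log axis) of 15 genes in fibroblast-like sums, with a point per library coloured by group and shaped by dog, and open symbols under the dotted line for 0 counts. TFPI2, KCNH1, GAP43, TNC and TIMP1 had 0 counts in both controls, and LIMS2 and C7 had 0 counts in the graft.

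In smooth muscle-like nuclei of the graft, MYH11, the smooth muscle myosin heavy chain, fell by 4.46 on the log2 scale (SE 1.01, adjusted p 0.0169), from 310 and 102 counts in the controls to 34. COL3A1 had 0 counts against 45 (at least 26.3-fold lower) and ADAM33 0 against 16 (at least 9.35-fold). The intermediate filament gene NES had 1 count against 32 (ratio 56.1, interval 9.38 to 2285) and CCDC88C 1 against 23 (ratio 40.3, interval 6.55 to 1662). AHNAK fell by 4.18 (SE 1.00). FSIP1 had 203 counts against 0 (at least 38.6-fold higher, adjusted p 0.00478). The serotonin receptor HTR2A had 82 against 0 (at least 15.6-fold), RUNX1 68 against 0 (at least 12.9-fold) and BNC2 120 against 2 (ratio 34.2, interval 9.27 to 286). COL12A1 (log2 fold change 5.28, SE 0.96) and LMCD1 (4.73, SE 0.93) rose. Without control dog 1 the limits were 8.46 for FSIP1, 3.42 for HTR2A, 2.84 for RUNX1, 5.00 for BNC2 and 15.99 for COL3A1. The ratio of NES came to 1.71 times its size, and the 2 counts left for ADAM33 give no fold.

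The test called 40 genes higher and 33 lower of 1120. The graft and distended vein enter this fit with 1 library each, so that the error rests on 2 control libraries of 42 and 20 nuclei, with 1 residual degree of freedom. Without distended dog 1 the count was 0. Of 24 extracellular matrix genes 4 rose and 2 fell, the same numbers as adjusted over the list alone, with tenascin-C, TNC, higher (3.62, SE 0.79) and elastin, ELN, at 1 count against 20 (ratio 35.1, interval 5.61 to 1454). Of 12 TGF-beta response genes 4 rose (5 adjusted over the list alone), among them RUNX1, TNC and LTBP1 (3.10, SE 0.84). Of 23 contractile genes MYH11 fell and MYOCD, a coactivator of contractile genes, rose with 66 counts against 1 (ratio 37.6, interval 6.52 to 1508), 1 and 1 also adjusted over the list alone. Among 13 mechanical response genes ANKRD1 rose with 38 counts against 0 (at least 7.22-fold), the 1 also adjusted over the list alone. Without control dog 1 the limit of ANKRD1 was 1.58 and the ratio of MYOCD 0.219 of its size, and without control dog 2 that ratio was 0.260 of it. Of 9 lists tested 0 were called by camera, with 0 past the threshold at an estimated correlation (lowest adjusted p = 0.711 with an estimated correlation). TGF-beta response genes, at 0.194 by camera, were past it by fry (0.0316) and by camera without the dominant features (0.0337).

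Control nuclei of this class lay in cluster 7 and the 37 grafted nuclei in cluster 17, which TNC, HTR2A, COL12A1, MYOCD and ANKRD1 lead. The fit held 42 and 20 control and 47 distended dog 1 nuclei, with no block possible. The dominant features took 30.5% and 57.9% of control and 3.02% of grafted UMIs. DESeq2 gave no adjusted p for 912 of the 1120 genes. The count of 73 was 131 with median-of-ratios scaling (65.6% higher against 54.8%, a shift of the median of 0.27 on the log2 scale). It was 16 in DESeq2, 6 without the expression filter, 31 with nuclei classed singly, 47 with thinned sums, 0 with doublets removed and 0 without distended dog 1. Smooth muscle-like nuclei of distended dog 2 numbered 1, so that no test was made there. Nor was it made for macrophage/monocyte-like nuclei, which numbered 9 and 26 in control, 90 and 4 in distended and 2 in grafted vein.

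**Figure D4:**
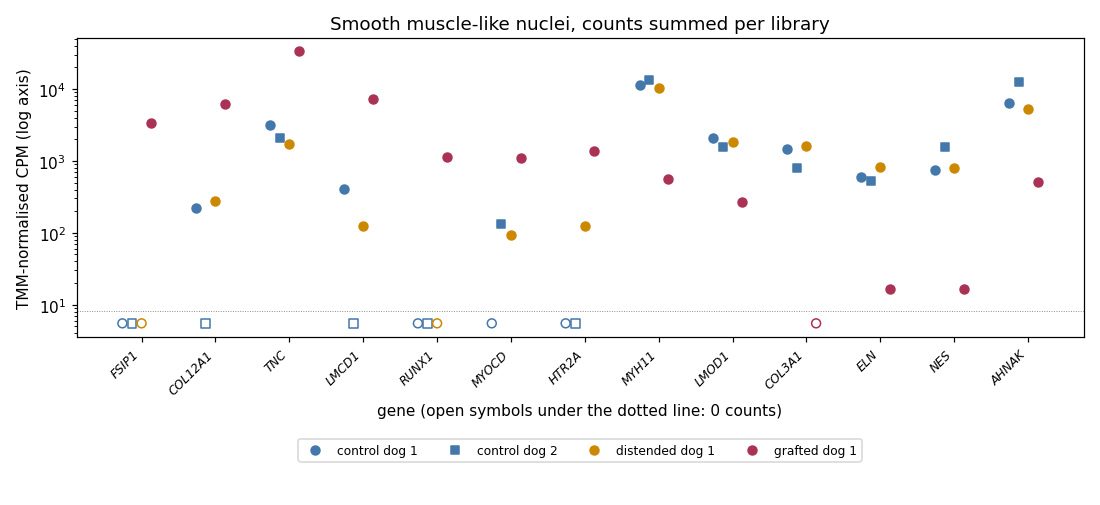
TMM-normalised CPM (log axis) of 13 genes in smooth muscle-like sums of 4 libraries, coloured by group and shaped by dog, with open symbols under the dotted line for 0 counts. FSIP1, RUNX1 and HTR2A had 0 counts in both controls, and COL3A1 had 0 counts in the graft.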

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

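The test of whether the graft effect differed between fibroblast-like and endothelial-like nuclei was chosen after the data were seen. It used edgeR on the sums of both classes with the library as a block.

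The graft effect differed between the classes for 7 of 11745 genes. Relative to endothelial-like nuclei, the graft effect in fibroblast-like nuclei was lower on the log2 scale for LIMS2 (-9.16, adjusted p 0.00325), LOC106559993 (-8.09, 0.00216), COL12A1 (-7.29, 0.0174) and the growth factor PDGFD (-6.06, 0.0253). PDGFD stood at 505 and 569 CPM in control fibroblast-like nuclei and at 11.3 in the graft, against 4.88, 3.01 and 7.46 CPM in endothelial-like nuclei. COL12A1 stood at 42.1, 155 and 9.88 CPM in fibroblast-like nuclei and at 0, 3.01 and 26.5 CPM in endothelial-like nuclei. Its counts in controls of dogs 1 and 2 were 1 and 27 in fibroblast-like and 0 and 1 in endothelial-like nuclei. Control fibroblast-like counts were 1 and 29 for LIMS2 and 0 and 16 for LOC106559993. The differences of these 3 genes thus rest largely on control dog 2.

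The difference between the graft effects was positive for LOC100855558 (8.04, adjusted p 9.60e-05) and LOC100855540 (7.72, 9.60e-05), whose levels in control dog 2 were 63.2 and 68.9 CPM in fibroblast-like and 7376 and 8063 CPM in endothelial-like nuclei. It rests on that library, since endothelial-like nuclei of control dog 1 held 1 and 0 counts. Both features head the leading genes of cluster 0, which also include the globin HBM. Whether they come from red cells was not tested. The number of genes was 43 without control dog 1, 2 without control dog 2, 6 without distended dog 1 and 7 without distended dog 2.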

How the results depend on the processing

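The clusters left out, the crossed block, the removal of the dominant features and the shares without a library were chosen after the data were seen. The other settings were planned. With 2 libraries per group and 1 graft, counts of called genes moved with most settings, and the cause was not tested except where fewer nuclei, counts or libraries entered the fit. In graft comparisons DESeq2 gave some genes no adjusted p, so its counts there come from fewer genes. Such genes numbered 3575 and 3064 of 13170 in whole vein, against control and against distended. They numbered 4028 of 10388 in endothelial, 4340 of 7222 in fibroblast and 912 of 1120 in smooth muscle sums. At 200 genes per nucleus, control dog 1 kept 7 fibroblast-like nuclei and left those fits.

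Whole vein counts, 0 in each comparison, were 1, 116 and 32 in DESeq2 for distended against control, grafted against control and grafted against distended, and 11, 287 and 144 without the expression filter. Grafted against control gave 4 with thinned nuclei. Leaving out a library gave 0 to 219, 0 to 646 and 0 to 432. The dog as a replicate block gave 0 in all 3.

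Endothelial distended against control, 24, gave 3 in DESeq2, 13 unfiltered, 7 with the dog as a replicate block, 0 with nuclei classed singly, 0 without the dominant features, 10 without the cluster led by DACH1, 6 without the cluster with globin, 4 with thinned sums and 0 to 151 without a library. Without the DACH1 cluster PLCB1 turned from 2.99 to -0.65. Endothelial grafted against control, 703, gave 175 in DESeq2, 0 with nuclei classed singly, 313 without the dominant features, 370 without the globin cluster, 68 with thinned sums and 192 to 1105 without a library; with the replicate block it gave 489, of which 447 were shared in direction.

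Fibroblast distended against control, 0, gave 0 to 2 without a library and 0 with the replicate block. Fibroblast grafted against control, 129, gave 51 in DESeq2, 22 unfiltered, 0 with the replicate block, 41 at 200 genes, 82 with nuclei classed singly, 38 without the dominant features, 0 with thinned sums and 3 to 245 without a library. Smooth muscle grafted against control, 73, gave 131 with median-of-ratios scaling, 16 in DESeq2, 6 unfiltered, 0 without doublets, 31 with nuclei classed singly, 47 with thinned sums and 0 without distended dog 1. A crossed replicate block gave 9, 138 and 20 in whole vein, 14 and 226 in endothelial and 0 and 4 in fibroblast comparisons. Of the list calls, the block changed no others than those given beside the results. Among genes picked by the rule, it left 2 of 6 calls in endothelial distended against control. It left 12 of 12 in endothelial and 0 of 12 in fibroblast grafted against control.

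Lists called in whole vein, 12, 11 and 16, were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry; distended against control gave 7 with thinned sums, and leaving out a library gave 8 to 15, 9 to 15 and 5 to 16.

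Nuclei thinned to 200 UMIs kept the dominant features, so their UMIs of other genes still differed between groups. Share differences, in percentage points, moved as follows. Endothelial distended minus control (-40.9) was -18.3 at resolutions 0.4 and 1.5, -12.8 with nuclei classed singly, 1.24 with thinned nuclei and -17.3 clustered without the dominant features; endothelial grafted minus control (-27.2) was -44.9 at resolution 1.5 and 4.21 thinned. Smooth muscle differences (-2.39 and -2.34) were 0.230 and 0.537 thinned. Clustered without the dominant features, no cluster was named macrophage/monocyte, so the 0 given for that class comes from the naming. Clusters that held 419 control dog 2 and 967 grafted nuclei also stayed unnamed there, so the endothelial shares of that clustering depend on the naming too. Macrophage distended minus control (1.12) was 0 in that setting and -0.183 to 2.43 without a library. Macrophage grafted minus control (-1.77) was 7.77 at resolution 1.5, 5.999 classed singly, 2.10 thinned and 0 in that setting.

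Not run for lack of libraries or nuclei: every smooth muscle distended and macrophage test, the graft comparisons without the graft, and for smooth muscle the replicate block, either control left out and 200 genes. No paired analysis was possible for smooth muscle because 4 libraries in 3 groups leave 0 residual degrees of freedom once the dog is added. Depth limits the controls, whose fibroblast-like sums without the dominant features held 7987 and 104998 UMIs.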

Other observations

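Of the tests below, the correlation without ribosomal protein genes was set before its result was seen and all others after.

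A cluster that the marker rule left unnamed, led by AQP9, MXD1, PLXNC1, NRG1, IL1RAP, SLC11A1 and PLEK, held 8 macrophage and 8 neutrophil markers. It made up 16.5% of grafted nuclei (447 of 2705, exact 95% interval 15.1 to 18.0). It made up 0 of 765 control nuclei in dog 1 (a share of up to 0.392%), 2.32% in control dog 2, and 0.332% and 0.830% in distended dogs 1 and 2. CSF3R, the receptor of granulocyte colony-stimulating factor, stood at 527.4 CPM in it and S100A12, a calcium-binding protein of granulocytes, at 444.1. A cluster with 15 T and NK lymphocyte markers, whose leading genes also included BCL11A, BLNK and IRF8, made up 1.37% of grafted nuclei and 0.131%, 0.772% and 0.142% of control dogs 1 and 2 and distended dog 1. In distended dog 2 it held 0 of 241 nuclei, a share of up to 1.24% that is not resolved from that of the graft. Lymphatic endothelial-like nuclei, led by MMRN1, SCN3A, PIEZO2 and LYVE1, made up 0.784% and 2.99% of control nuclei, 5.60% of distended dog 1, 0 of 241 in distended dog 2 (a share of up to 1.24%) and 0 of 2705 in the graft (up to 0.111%). Clustered without the 4 dominant features, nuclei named lymphatic endothelial-like made up 2.48% of the graft (67 of 2705). They were 0.415% of distended dog 2 (1 of 241). In the main clustering, 64 grafted nuclei and 1 of distended dog 2 lay in an unnamed cluster led by MME. It carried PROX1 (959 CPM) and FLT4 (1254 CPM), with MMRN1 at 219 and LYVE1 at 7.6 CPM. The lymphatic endothelial-like cluster held MMRN1 at 11366 and LYVE1 at 1637 CPM. Whether the 67 nuclei are those of the MME cluster was not tested. Grafted nuclei high in MMRN1 and LYVE1 are thus not shown by either clustering.

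A cluster led by the venular chemokine receptor ACKR1, TIMP1 and ribosomal protein genes made up 8.98% of grafted nuclei, 3.92% and 0.0965% of control and 1.04% and 4.15% of distended nuclei. A cluster led by MME, SH3GL3 and ANO4 made up 1.31%, 2.99%, 1.80%, 0.415% and 2.37% of control dogs 1 and 2, distended dogs 1 and 2 and the graft. A cluster led by RN7SL1, DNAJB1, RPPH1 and the chaperone genes HSP70 and HSPH1 made up 50.6% of distended dog 2 (122 of 241) and 2.11% of the graft, and 0.131%, 0.676% and 0.142% of control dogs 1 and 2 and distended dog 1.

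The library labelled distended of dog 2 lay near the graft: across 7222 genes of fibroblast-like nuclei its difference from control dog 2 correlated with that of the graft from control dog 1 at 0.4002, against -0.140 for distended dog 1 with the controls exchanged. Across 10388 genes of endothelial-like nuclei the values were 0.514 and -0.0584. Genes are not independent replicates. For ribosomal protein transcripts as the source the test decides nothing. The correlation was 0.398 without these 76 genes, but 0.337 was left even without the 76 genes that added most to it, so that leaving out so few genes could not have halved it. A swap of labels with the graft stays open. Of grafted fibroblast-like nuclei 0% (a share of up to 0.379%) lay in clusters of control and distended dog 1 nuclei, but of those from distended dog 2 only 1 of 50 did, so that either labelling leaves a distended library outside them. A single wrong label, a difference in handling and a difference between the dogs stay open and untested.

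In the control libraries 4 features took most of the counts. Different cell classes as the source are argued against, since those features took 1.96% of UMIs in grafted and 75.9% and 66.2% in control endothelial-like nuclei. The depth of nuclei is argued against as well, since in endothelial-like nuclei of 500 to 1000 UMIs the median was 7.74% in the graft and 52.4% and 58.2% in the controls. RNA quality, library handling and the treatment itself stay open, since each goes with the groups.

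Genes called between distended and control endothelial-like nuclei may come from a change in the clusters that make up the class. Without the cluster led by DACH1, the median log2 fold change of the genes called higher was 3.25, against 4.21 with it, over 13 of 15 genes tested in both, with 2 still called, HMGA2 and SMCO2. Without the cluster whose leading genes included the globin HBM, the median of the genes called lower was -3.65, against -4.32, over 6 of 9, with VCAM1 the 1 still called. HBM, LOC480784 and SOX6 were no longer tested there. The first median kept 0.771 of its size (95% interval 0.439 to 1.05 over 10000 draws of the genes) and the second 0.843 (0.306 to 1.02). The median SE went from 0.91 to 1.43 and from 0.91 to 1.08, so that calls ended with smaller folds and larger errors alike. In the set called higher, 5 of the 13 genes had 0 control counts, where a fitted fold hangs on the prior count. Both intervals reach from under 0.5 of the size to all of it, so the shift between clusters and a change within them cannot be told apart for these sets.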
